A study of Mus musculus with 7 samples.

How the data were processed

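The series holds 6 H3K27ac ChIP-seq libraries and 1 input library from RAW 264.7 cells of 2 genotypes, WT and Parp14 KO, at 3 times, untreated and after 1 h and 2 h of LPS. Groups were taken from the genotype and treatment labels. Each group is 1 library. Per the submitters' processing notes, Bowtie2 2.2.6, SICER 1.1 and the builds mm10 and GRCm38 are named, without their roles. The authors deposited 1 list of islands per library with a position and a whole-number read count for each island. Island borders lie on a grid of 200 bp, and the names of the H3K27ac lists carry settings that read as a window of 200 bp, a gap of 600 bp and a false discovery rate of 0.01. The settings for the input list, the control library used in calling and the treatment of duplicate reads are not given in the sources used here. Reads outside islands are not in the lists, so a library's total depth is unknown, and a region with no island has an unknown count below the caller's threshold. Islands were called per library, which means that a region can drop out of a shallow library. Reads in islands ranged from 7188405 to 16483142 per H3K27ac library, and the input list held 1912786 reads in 20444 islands. The input is labelled RAW 264.7, but the name of its list carries BM, which the labels do not explain, and its description names H3K27ac although its antibody is given as none, so the origin of its cells is not certain.

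From these lists the islands of the 6 H3K27ac libraries were merged where they overlapped by at least 1 bp or touched, and each library's reads were summed per merged region. A library with no island in a region was given the 5th percentile of its own island counts, between 25 and 59 reads. Positions are printed from 1 in mm10. Counts were normalized with TMM and regions with a mean of at least 50 reads were tested. The main test was edgeR's quasi-likelihood F test (edgeR 4.0.16, R 4.3.3) with time and genotype as additive terms, 2 residual degrees of freedom, 2-sided, with Benjamini-Hochberg adjustment over 22818 regions at 0.05. The common dispersion was 0.0277. With no replicates within a group, the spread comes from how far the genotype difference varies between times and the LPS response between genotypes. Nothing in the labels says that the libraries came from separate cultures, so the p-values measure only the spread between these libraries, which may be partly technical. The KO cells are, as far as the labels say, a single line compared with the parental kind, so that line and genotype are confounded. Standard errors were derived from the log2 ratio and the F statistic and are approximate. The test was checked on simulated counts for 22818 regions: for KO against WT it recovered 74% of 2-fold and 100% of 4-fold changes with 4 false calls, and for LPS 1 h against untreated 65% and 100% with 16 false calls. These counts, and the simulated pairs of unchanged libraries given below, were drawn with the common dispersion for every region. They held no filled values. Beyond the changes put in, they held no LPS response and no genotype difference that varied with time. The few false calls thus do not show the error rate of the test on the real counts.

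Pairs of libraries were compared without a test, as the log2 ratio of normalized reads plus a pseudocount of 5, with an exact Clopper-Pearson 95% interval of the ratio. A region passed the size rule when it differed at least 2-fold, its interval excluded 1 and the higher library had at least 50 reads. The reads carry no molecular identifiers, so these intervals cover counting error only. The 11 gene lists (LPS early response, LPS late response, interferon-stimulated, TLR4 and type I interferon pathway, PARP family, macrophage identity, IL-4 and STAT6 response, sterol and LXR, osteoclast, housekeeping and other cell types) were fixed before the data were examined, as were the tests, the rule for named genes and the other settings listed below. The PARP family list shares 3 genes, Parp9, Parp10 and Parp12, with the interferon-stimulated list. It also holds Parg, Adprs, Macrod1, Macrod2 and Oard1, which are not PARP genes. A list's median was set against 10000 random lists of the same number of regions, matched in 10 bins of mean reads, as a description of these libraries. Bootstrap intervals of a median resample its regions within the same libraries, so they hold no noise between libraries or cultures.

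The annotation used here, of assembly GRCm38.p6, gives the span of each gene without its strand or transcription start. The planned assignment to promoters was therefore replaced: a region belonged to a gene when it overlapped the gene's span extended by 1000 bp, a gene took the overlapping region with the most reads, and other regions were called intergenic and given the nearest coding gene within 50 kb, as a neighbour and not as a target. The other settings meant for the start became the span extended by 2500 bp and the sum of regions within 10 kb of the span. Wide regions can cover several genes, which are then named together.

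The named regions were, for KO against WT, LPS 1 h and LPS 2 h, the 10 gene regions with the largest increase and the 10 with the largest decrease and the 3 intergenic regions of each direction, among those past the threshold with the same sign in every pair of libraries, together with Parp14 and the 3 members of each list with the largest absolute log2 ratio whether called or not. For the difference of responses they were the 5 gene regions of each direction with the largest mean difference over 1 h and 2 h among those with the same sign at both. Predicted genes, pseudogenes and RNA genes were passed over where the region also held a coding gene. Regions without a coding gene are in the counts and mostly not named in the text, and some named members of the lists are not reported here. Stretches of the genome shifted between the genotypes were sought in windows of 10 Mb with at least 10 regions, as medians beyond 0.4 on the log2 scale at all 3 times, and their borders were set where a running median of 15 regions crossed 0.25.

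The alternatives were other scalings (DESeq2 size factors, total reads in islands, size factors from the housekeeping list, cyclic loess offsets), the DESeq2 Wald test (DESeq2 1.42.0), minimum means of 20 and 200 reads and none, other fills (0 reads, the 25th percentile, only regions with islands in all 6 libraries), other ways to form regions (gaps of 2000 bp, islands of at least 50 reads, islands in at least 2 libraries), autosomes only, each library left out, the median of the surrounding 10 Mb subtracted, pseudocounts of 1 and 20, a loess trend removed per pair, and a size rule of 1.5-fold. Leaving out the shifted stretches and the term for KO at 1 time were added after the data were seen. The input list entered no comparison between groups and is described on its own. Tables were handled in Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and statsmodels 0.14.6, and figures were drawn with matplotlib 3.10.9.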

Results

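H3K27ac, the acetylation of lysine 27 on histone H3 that marks active promoters and enhancers, was mapped by chromatin immunoprecipitation and sequencing (ChIP-seq) in RAW 264.7 cells, a mouse macrophage line. The cells were wild type (WT) or carried a knockout (KO) of Parp14, a member of the PARP family that attaches ADP-ribose to proteins. Cells of each genotype were left untreated or given lipopolysaccharide (LPS), a component of the bacterial cell wall sensed by TLR4, for 1 h or 2 h. Each of the 6 combinations was measured in 1 library, and 1 input library accompanied them. The WT libraries held 8468851 reads in 23518 islands untreated, 15007657 reads in 25996 islands at 1 h and 10605836 reads in 24869 islands at 2 h. The KO libraries held 15834486 reads in 24137 islands untreated, 16483142 reads in 27651 islands at 1 h and 7188405 reads in 26029 islands at 2 h. The islands covered between 111 and 132 Mb per library. Overlapping islands merged into 29813 regions, of which 16479 held an island in all 6 libraries and took 95.2% of the reads, and 22818 regions had enough reads to be tested. There were no replicates within a group, so intervals given for a ratio of 2 libraries cover counting error only.

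The targeted gene was examined at the outset. The region over Parp14 (mm10 chromosome 16, 35866001 to 35873999) held an island in all 6 libraries, KO included. Its normalized reads were 758, 1278 and 3160 in WT untreated, at 1 h and at 2 h, and 579, 710 and 1998 in KO. Averaged over the 3 times the KO value was 1.55-fold lower (log2 ratio -0.64, approximate SE 0.10, edgeR adjusted p = 0.0367), and it was lower at each of the 3 times. The call was lost when the median of the surrounding 10 Mb was subtracted (log2 ratio -0.56) and without any 1 of the 6 libraries. It was also lost with a fill of 0 reads or of the 25th percentile where no island was called. No value of this region was filled, so the fills act on its call only through the fit and adjustment over other regions. With a fill of 0 reads no region was called between KO and WT. The region rose 3.78-fold at LPS 2 h over both genotypes (edgeR adjusted p = 0.000587). Acetylation at the gene does not show whether its product was made, so these values do not check the knockout, and where the gene was disrupted is not stated in the labels.

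The response to LPS was compared with untreated cells over both genotypes. At 1 h the classical early genes of the macrophage response rose. Of the 46 regions of the LPS early response list, 35 rose and 1 fell, with 38 and 1 when adjusted over the list alone, and the list's median was 1.90-fold above untreated, above all 10000 random lists of matched read number. The region over Il1a, which encodes the cytokine interleukin-1 alpha (chromosome 2, 129294401 to 129343599, shared with Ckap2l), rose 5.96-fold (log2 2.58, SE 0.11, edgeR adjusted p = 0.000782, higher in both genotypes). Those over Dusp2, a phosphatase of MAP kinases, and Il10, an anti-inflammatory cytokine whose region also covers Mapkapk2, rose 4.33-fold and 3.96-fold. The region over Fos, an immediate-early transcription factor, was the list's member that fell, with a log2 ratio of -1.25. In the LPS late response list 8 of 17 regions rose and 1 fell, led by Slc7a11 (4.74-fold), a cystine transporter, Cd40 (4.06-fold), a costimulatory receptor, and the region shared by Fpr1 and Fpr2 (4.02-fold), receptors for formylated peptides.

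Among the interferon-stimulated genes the response at 1 h was mixed. In that list 8 of 62 regions rose and 3 fell, and the median log2 ratio was -0.02. Ccl5, a chemokine, rose 3.83-fold, and Slfn2 rose 2.32-fold. Ifi47, an interferon-inducible GTPase, fell 2.72-fold, a call lost without any 1 of the untreated or 1 h libraries. In the macrophage identity list 6 of 23 regions fell and 3 rose. The largest falls were at Mertk (3.23-fold), a receptor for apoptotic cells, Fcgr3 (2.69-fold) and Fcgr1 (2.59-fold), both receptors for IgG. Mertk was not called without WT untreated, nor Fcgr1 without WT LPS 1 h. This list's median log2 ratio of 0.00 turned negative under each other scaling, down to -0.23, and its 3 rises were 0 under total reads and under cyclic loess offsets. In the list of TLR4 and type I interferon pathway genes 10 of 26 rose and 1 fell. Its 3 largest changes were at the kinase gene Ikbke (2.22-fold), the adaptor gene Ticam1 (1.94-fold) and Socs1 (1.92-fold), an inhibitor of cytokine signalling.

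Most of the regions with the largest increases at 1 h had no island in at least 1 untreated library. A region over Src and Manbal (chromosome 2, 157392001 to 157440999) had no island in either untreated library and held 1704 normalized reads in WT and 1260 in KO at 1 h. The same held for regions over Alpk2 (1217 in WT, 1713 in KO), the span of Nfkb1 (757 and 921) and Nes and Bcan (639 and 1019). Regions over Lpp (826 and 868) and Rbfox1 (541 and 2052), and an intergenic region whose nearest coding gene was Dusp5 (662 and 1009), had an island in 1 of the untreated libraries, with at most 88 normalized reads. Their fold changes depend on the value assigned where no island was called, and are not given. Among coding genes the largest decreases were at Abo, Cadm1, Cntrl, Sgcz, Nfia and Mrpl1. Of these, only the region in Sgcz (chromosome 8, 37875601 to 37905999) kept an island in all 6 libraries, and it fell 11.5-fold, from 3108 to 254 normalized reads in WT and from 3405 to 314 in KO (edgeR adjusted p = 0.00102).

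In all, 3496 of 22818 regions rose at LPS 1 h and 3798 fell (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted, 2-sided). Under scaling by total reads in islands the split was 2711 and 4814. The total of 7294 moved to 2882 without the KO LPS 1 h library, 2570 without KO untreated, 3033 without WT LPS 1 h and 3523 without WT untreated, each leaving 1 residual degree of freedom. It was 4659 when regions needed 200 reads and 4513 when regions without an island were set to 0 reads. The direction of the split depended on the fill, with 2793 higher and 1720 lower for 0 reads and 4284 and 2168 for the 25th percentile.

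At LPS 2 h more regions of the LPS early, LPS late and interferon-stimulated lists were called higher than untreated than at 1 h. In the LPS early response list 38 of 46 regions were higher than untreated and 1 (Fos) was lower, with a median of 2.81-fold. Il1a rose 10.9-fold, Tnfaip3, a feedback inhibitor of NF-kB, rose 6.74-fold (log2 2.75, SE 0.10, edgeR adjusted p = 0.000252), and the shared region of the chemokine genes Cxcl1 and Cxcl2 rose 6.56-fold. In the LPS late response list 14 of 17 rose and none fell. Cd40 rose 13.9-fold, the Fpr1 and Fpr2 region 11.4-fold and Slc7a11 9.19-fold. In the interferon-stimulated list 34 of 62 regions rose and 1 (Pml) fell, or 37 and 1 when adjusted over the list alone. Ccl5 rose 17.3-fold, and Gbp3 and Ifit1 each rose 6.02-fold. In the TLR4 and type I interferon pathway list 13 of 26 rose and 2 fell. The region over Ifnb1, the gene of interferon beta, rose 4.37-fold (log2 2.13, SE 0.31, edgeR adjusted p = 0.00512), Ikbke rose 3.67-fold and the region of Tyk2 and Cdc37 rose 3.06-fold.

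Other lists split. In the macrophage identity list 9 of 23 regions fell at 2 h and 3 rose, with Fcgr3 4.02-fold and Mertk 2.66-fold lower. In the list of genes of the IL-4 and STAT6 response 6 of 16 rose and 3 fell at 2 h. Those that rose included the chemokine genes Ccl17, which had no island untreated and 1385 normalized reads in WT and 1176 in KO at 2 h, and Ccl22 (424 and 322), and the growth regulator Myc (5.94-fold). In the osteoclast list 4 of 11 rose and 2 fell (2 and 3 under housekeeping size factors, 3 and 4 under cyclic loess offsets), with the protease gene Mmp9 9.04-fold higher and the proton pump subunit gene Atp6v0d2 4.60-fold lower. In the sterol and LXR list 1 of 18 rose, the cholesterol exporter Abca1 (2.34-fold), and 3 fell, among them Srebf1 (1.60-fold) and Scd2 (log2 -0.59). In that list 5 fell under total reads, 6 under housekeeping size factors and 4 under cyclic loess offsets. In the PARP family list 8 of 21 rose, led by Parp14 itself and followed by Macrod2 (2.05-fold), which is not a PARP gene. In the same list 4 fell, among them Parp8 (1.75-fold). In the housekeeping list 7 of 20 rose and 3 fell, with Eef1a1 1.45-fold higher and Gusb lower (log2 -0.56) as the largest changes, while 2 rose and 4 fell under total reads and under housekeeping size factors, and 3 and 4 under cyclic loess offsets. Of 30 marker genes of other cell types, 12 overlapped an island and 7 regions were tested. At 2 h 4 of these fell and 1 rose, with the region of Elane, a neutrophil protease, 2.63-fold lower. Without KO untreated the calls at Macrod2, Scd2, Eef1a1 and Gusb were lost, without WT untreated those at Mertk, Scd2 and Eef1a1, and without KO LPS 2 h that at Macrod2. The medians of the macrophage identity, IL-4 and STAT6, and sterol and LXR lists at 2 h lay within 0.07 of 0 on the log2 scale and changed sign under another scaling.

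Across the genome 4748 regions rose at 2 h and 5080 fell. Among coding genes the largest increases were again at regions with no island in at least 1 untreated library, over Src and Manbal (5517 normalized reads in WT, 4815 in KO at 2 h), Alpk2 (3762 and 5176), Lad1 and Tnni1 (2233 and 2597), Ttyh2 and Dnaic2 (2217 and 2305), Atp8b4 (1845 and 2215), the adenosine receptor gene Adora2a (2474 and 2444), Nfkb1 (2015 and 1766) and Akap13 (2449 and 1561). The largest decreases at coding genes were at St6gal1 (18.0-fold), Zdhhc14, Sgcz (15.4-fold), Icos, Tgfbi, Dtnb, Arhgap24 and Ppp2r5c (11.4-fold). The split was 3528 and 6514 under housekeeping size factors and 3647 and 6341 under total reads, since these scalings moved the median of all regions from -0.03 to -0.18 and -0.16. It was 3956 and 3311 with a fill of 0 reads and 3897 and 3412 with the 25th percentile. Leaving out KO untreated or WT untreated moved the total of 9828 to 4858 and 5096.

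Between 1 h and 2 h of LPS 1258 regions rose and 1274 fell. The LPS late response list had 13 of 17 regions higher at 2 h than at 1 h, or 17 when adjusted over the list alone. The interferon-stimulated list had 24 of 62 higher, or 37 when adjusted over the list alone, and 1 lower. The LPS early response list had 17 of 46 higher and 1 lower, and 6 of the 18 sterol and LXR regions were lower. The split was 1129 and 1764 under housekeeping size factors and 1670 and 1102 in the DESeq2 test. Leaving out WT LPS 1 h gave 0 regions by edgeR (2532 with all libraries), KO LPS 1 h 343, KO untreated 1437, WT LPS 2 h 1439 and WT untreated 1463, and setting regions without an island to 0 reads also gave 0 by edgeR, with 4906 at an unadjusted p under 0.05.

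The response was also described within each genotype, without a test. At 1 h 1677 regions were at least 2-fold higher than untreated in WT and 3094 lower, and 2452 and 3015 in KO. Removing a loess trend changed the splits to 2013 and 2369 in WT and 2652 and 2493 in KO, and a fill of 0 reads to 3736 and 3384 in WT and 4128 and 4116 in KO. At 2 h the counts were 2830 and 3573 in WT and 3105 and 3209 in KO. They were 3204 and 2941 in WT and 3479 and 2524 in KO with the loess trend removed, and 4439 and 4511 in WT and 3161 and 5703 in KO with a fill of 0 reads, so the direction of these splits depended on the processing. These counts are over 29813 regions, while simulated pairs of unchanged libraries, over the 22818 tested regions, gave between 58 and 117 per direction. Over 16389 regions with islands in all 6 libraries, the log2 responses of WT and KO correlated with Pearson's r of 0.887 at 1 h and 0.867 at 2 h. These correlations are across regions, which are not independent replicates.

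KO was compared with WT, the question the series' design text names, over the 3 times. Few regions of the innate immune genes were called. Ifnb1 (chromosome 4, 88510801 to 88528599) was 3.83-fold lower in KO (log2 -1.94, SE 0.25, edgeR adjusted p = 0.0239), at all 3 times: its normalized reads were 168, 321 and 1045 in WT and 75, 61 and 229 in KO. Nos2, the inducible nitric oxide synthase, was 2.24-fold lower (adjusted p = 0.0445) and Atf3, a transcription factor of the LPS early response list, 1.81-fold lower (adjusted p = 0.0164). Oas2, an antiviral oligoadenylate synthetase, and Lgals3bp were the members of the interferon-stimulated list lower by this average over times, with log2 ratios of -0.57 and -0.60. They were named after their values were seen, and neither passed when adjusted over the list alone. With islands merged across gaps of 2000 bp the enlarged region holding Ifnb1 had a log2 ratio of -1.21 (edgeR adjusted p = 0.104). The Ifnb1 call was also lost without either LPS 1 h library (log2 ratio -1.71 without WT, -1.69 without KO), the Nos2 call without any untreated or 1 h library, and the Atf3 call without WT LPS 1 h or either untreated library.

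Most of the widest differences between the genotypes at gene regions were where at least 1 library had no island. Higher in KO were a region over Mir100hg and Mir125b-1, a noncoding host gene and a microRNA gene (chromosome 9, 41570601 to 41595399), with no island in WT untreated, 47 and 62 normalized reads in WT at 1 h and 2 h and 786, 2232 and 1959 in KO, and regions over Cd244a, an immune receptor, Thsd4, Hpgd, which encodes a prostaglandin dehydrogenase, Fam161a, Trp53i11 and Smad1, a transducer of BMP signals. In the Cd244a region WT had no island, and KO held 451, 750 and 531 normalized reads. Lower in KO were regions over Fat3, Pla2g7, which encodes a phospholipase that degrades platelet-activating factor, Slc24a5, Pax3, Cyfip2, Gpnmb, Cd200r3 and the predicted gene Gm18224. The Fat3 region (chromosome 9, 16032401 to 16049999) held 635, 598 and 711 normalized reads in WT and had no island in KO. An intergenic region whose nearest coding gene was Cd93 held 1506, 264 and 176 normalized reads in WT and 180 in KO untreated, and had no island in KO at either LPS time. The region over Pax3 kept islands in all 6 libraries and was 10.0-fold lower in KO, at each of the 3 times (edgeR adjusted p = 0.00479). The calls at Mir100hg and Mir125b-1, Cd244a, Gm18224, Fat3, Slc24a5 and Pax3 stood with each library left out, and each other one named here was lost without at least 1 untreated or 1 h library. Leaving out either library of a time removes that time from the genotype comparison. At Cd244a all WT values and at Fat3 all KO values were filled, so for these 2 regions the check says little. With a fill of 0 reads no region was called.

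By gene list, KO and WT differed at few regions when averaged over the 3 times. In the LPS early response list Birc3 was higher in KO and Atf3 lower. Nos2 and Il1rn were lower in the LPS late response list. In the TLR4 and type I interferon pathway list Tirap was higher and Ifnb1 lower, in the PARP family Parp6 was higher and Parp14 lower, and in the osteoclast list Car2 (log2 -0.58) and Atp6v0d2 (1.47-fold) were lower. Cd3d, a T cell gene, was higher in the list of other cell types. None of the 23 macrophage identity, 16 IL-4 and STAT6 or 18 sterol and LXR regions passed. Adgre1, the macrophage marker F4/80, had a log2 ratio of -0.82 (adjusted p = 0.0537), and Ctsk, an osteoclast protease, one of -1.62 (adjusted p = 0.111). Birc3, Tirap, Parp6 and Cd3d lie on chromosome 9 between 3334401 and 67854199, where regions were higher in KO as a whole, and none of these 4 passed once the median of the surrounding 10 Mb was subtracted. The calls in these lists that were followed in the fits with a library left out were each lost without at least 1 library. Il1rn, Oas2 and Lgals3bp were not among those followed.

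The higher regions were concentrated in 2 stretches of the genome. On chromosome 9 from 3334401 to 67854199, 446 regions with islands in all 6 libraries had a median KO to WT ratio of 1.47 untreated, 1.43 at 1 h and 1.40 at 2 h. On chromosome 4 from 150831201 to 156240399, 67 such regions had ratios of 1.95, 1.73 and 1.93. Above 0 on the log2 scale were 93.7% and 98.5% of these regions, against 51.8% of the 15876 regions elsewhere. Since the stretches were chosen for such ratios, these shares follow in part from the choice. Of the regions called higher in KO, 47.7% lay there.

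**Figure D1:**
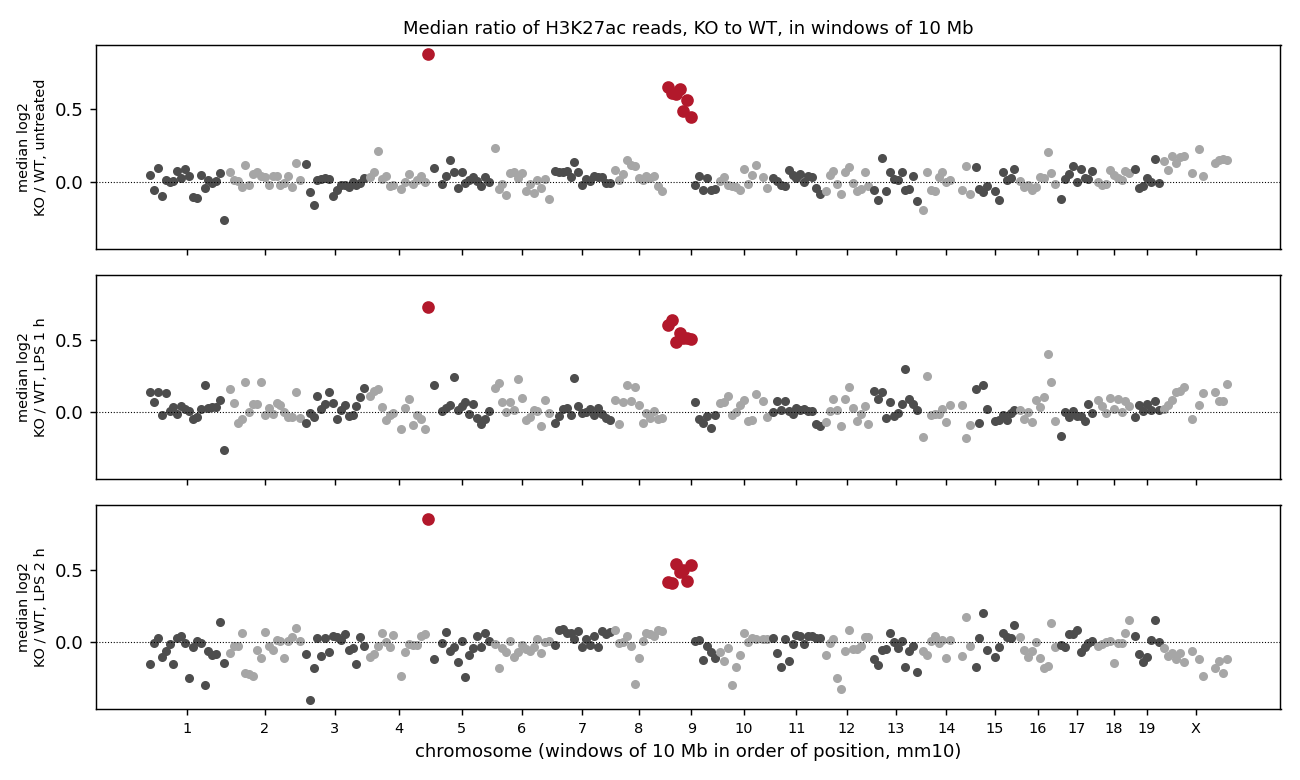
Median log2 ratio of H3K27ac reads in KO to WT (vertical axis) in windows of 10 Mb in genome order (horizontal axis), for untreated cells and for LPS 1 h and 2 h, with 1 library per genotype and time. Red points mark the windows shifted by more than 0.4 at all 3 times, which lie on chromosome 9 and at the end of chromosome 4, and the shades of grey alternate by chromosome.

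Over the genome 570 regions were higher and 516 lower in KO (edgeR quasi-likelihood test, adjusted p threshold 0.05), out of 22818. Of these calls 272 higher and 5 lower lay in the 2 stretches, and 298 higher and 511 lower outside them. The count of 1086 became 577, of which 221 were higher and 356 lower, when the other regions were refitted without those 2 stretches. Calls outside the stretches were thus also lost in the refit. The count was 570, with 200 higher and 370 lower, when the median of the surrounding 10 Mb was subtracted. It became 1873 in the DESeq2 test, 706 when regions without an island were given the 25th percentile and 0 when they were given 0 reads (edgeR, 3393 at an unadjusted p under 0.05), and leaving out a library gave 31 (WT LPS 1 h), 59 (WT untreated), 63 (KO untreated), 163 (KO LPS 1 h), 1511 (WT LPS 2 h) or 1559 (KO LPS 2 h). At single times and without a test, 522 regions were at least 2-fold higher and 1318 lower in KO untreated, 1084 and 1048 at 1 h, and 812 and 1213 at 2 h, over 29813 regions, where simulated unchanged pairs over the 22818 tested regions gave between 64 and 116 per direction. With a fill of 0 reads these became 2654 higher and 1734 lower untreated, 2269 and 1725 at 1 h and 938 and 2067 at 2 h, so the direction untreated depended on the fill, and the split at 1 h turned to 1046 and 1115 with a loess trend removed and to 941 and 1218 under total reads. The log2 ratios of KO to WT correlated across regions with r of 0.684 between untreated and 1 h, 0.470 between untreated and 2 h and 0.457 between 1 h and 2 h.

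The difference of the LPS response between the genotypes was largest, among the 11 lists, for the interferon-stimulated genes at 2 h. Between untreated cells and 2 h the median of the 62 regions was 2.37-fold in WT and 1.32-fold in KO. The median log2 ratio of KO to WT was -0.03 untreated, -0.16 at 1 h and -0.81 at 2 h, the last 1.76-fold lower and below all 10000 random lists, whose central 95% lay between -0.06 and 0.09. At 2 h 55 of the 62 regions were below 0. At 1 h 45 were, and the median of -0.16 was also below all 10000 random lists (-0.05 to 0.08). By the size rule 20 of 62 were at least 2-fold lower in KO at 2 h and none higher, where 182 of 9754 gene regions would give 1.16, and none was lower untreated or at 1 h. The difference of the responses, KO minus WT, had a median of -0.07 at 1 h and -0.79 at 2 h. For the LPS early response list these medians were 0.04 and -0.01, for the LPS late response list -0.10 and -0.33, and for the housekeeping list -0.03 and 0.03. The interval of the -0.33 for the LPS late response list spanned 0 (bootstrap 95%, -0.61 to 0.25), though this median was below all 10000 random lists. That list's median log2 ratios of KO to WT were -0.17 untreated (-0.58 to 0.15), -0.20 at 1 h (-0.45 to -0.00237) and -0.35 at 2 h (-0.63 to -0.04), the last below all random lists, with 13 of 17 regions below 0 and 2 called lower over the 3 times.

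Named for the lowest ratios at 2 h, after their values were seen, were Gbp5, Oasl2, Ifi44, Zbp1 and Mx2. Mx2, an antiviral GTPase (chromosome 16, 97532801 to 97539399), rose 3.42-fold in WT and 1.27-fold in KO by 2 h, and its KO to WT ratio was 0.315 at 2 h (exact Clopper-Pearson 95% interval 0.265 to 0.364). Usp18, which removes the ubiquitin-like protein ISG15 (chromosome 6, 121243601 to 121253599), rose 2.43-fold in WT and 1.14-fold in KO, with a ratio of 0.377 (0.340 to 0.414). Irf7, the transcription factor that amplifies interferon production (chromosome 7, 141263601 to 141266999), rose 2.90-fold and 1.30-fold, with a ratio of 0.487 (0.403 to 0.575). Ifit2 stood 1.81-fold above untreated in WT and at 0.487 of it in KO, with a ratio of 0.415 (0.324 to 0.509). Zbp1, a sensor of nucleic acids, had a ratio of 0.312, and Ifi44 one of 0.266. Gbp5 and Oasl2 had islands in 2 of the libraries only. Ccl5 rose 23.4-fold in WT and 12.8-fold in KO, and Cxcl10 2.47-fold and 1.46-fold. Not all members went this way. Isg15, which lies in the raised stretch of chromosome 4, rose 4.05-fold in WT and 4.61-fold in KO, Slfn2 2.76-fold and 3.74-fold, and Cd274, which encodes PD-L1, 3.53-fold and 3.43-fold. In the early list Nfkbia rose 3.51-fold in WT and 3.45-fold in KO, and Tnfaip3 6.50-fold and 6.94-fold.

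**Figure D2:**
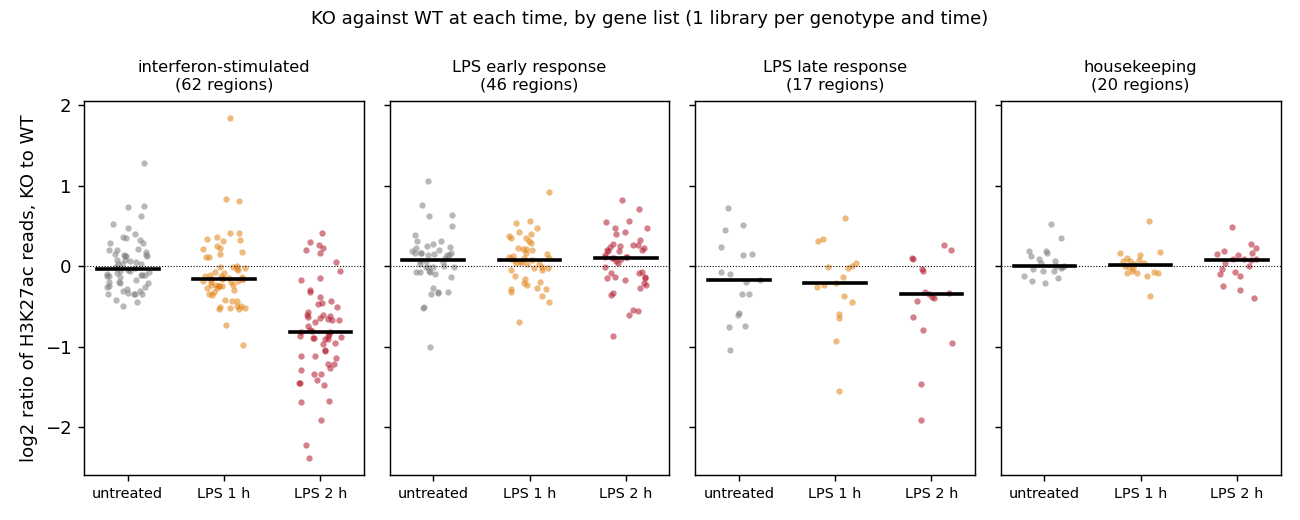
Log2 ratio of normalized H3K27ac reads in KO to WT (vertical axis) per region at each time (horizontal axis), for 4 gene lists. Points are regions, horizontal bars are medians and the dotted line marks 0. The interferon-stimulated median is -0.81 at 2 h and the LPS late response median -0.35, against 0.11 for the LPS early response list and 0.08 for the housekeeping list.

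**Figure D3:**
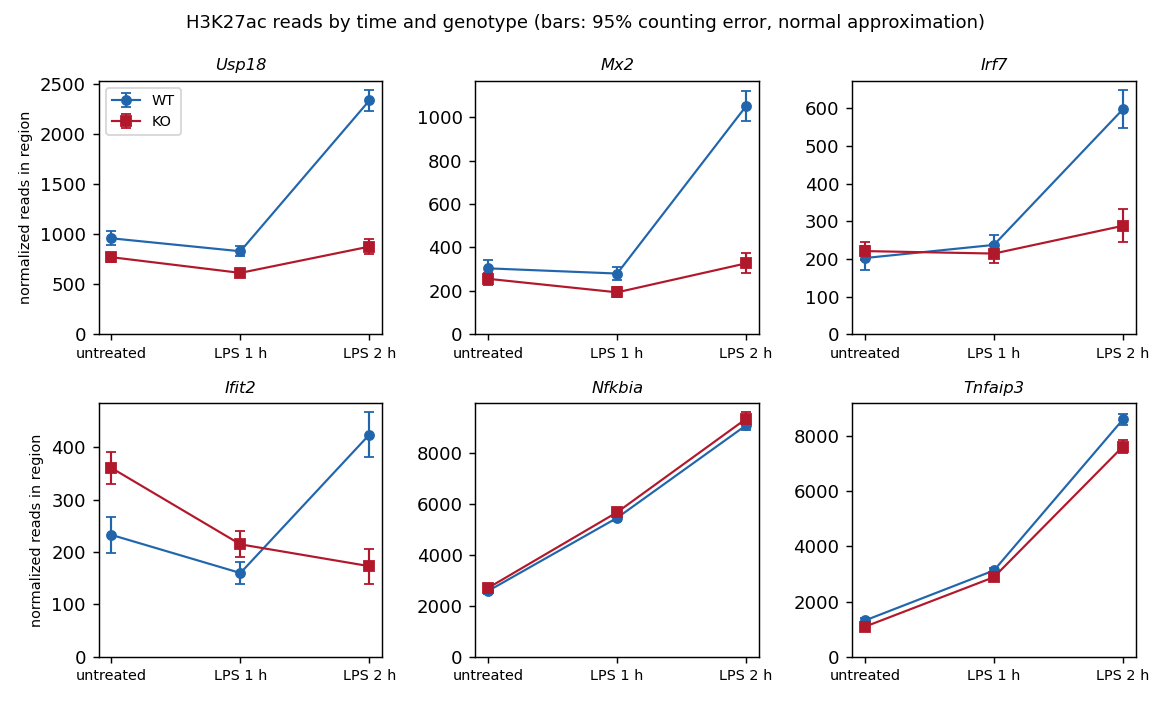
Normalized H3K27ac reads in the region of each gene (vertical axis, from 0) untreated and at LPS 1 h and 2 h (horizontal axis) in WT (blue circles) and KO (red squares), with 1 library per point and 95% counting error as bars. Usp18, Mx2, Irf7 and Ifit2 are lower in KO at 2 h, with ratios of 0.377, 0.315, 0.487 and 0.415, while Nfkbia has a ratio of 1.03 and Tnfaip3 one of 0.886.

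These differences rest on the KO and WT libraries at 2 h, of which the KO library had the fewest reads in islands of the 6, and the planned comparison of responses has no test. A test chosen after the values were seen, an edgeR term for KO at 2 h beside the additive model with 1 residual degree of freedom, called 0 of 22818 regions when adjusted over all regions and 1254 lower and 1080 higher at an unadjusted p under 0.05. Of the 62 interferon-stimulated regions 37 were lower at an unadjusted p under 0.05 and none higher. Adjusted over the list alone 35 passed. In the other lists, adjusted in the same way, 4 regions passed and are named after their values were seen: Ccl24 (adjusted p = 0.00427) and Tgm2 (0.0118) of the IL-4 and STAT6 list were higher, and Parp12 (0.0346) of the PARP family, also in the interferon-stimulated list, and Cybb (0.0451) of the macrophage identity list were lower. The corresponding terms for KO untreated and KO at 1 h called 0 regions over the genome and 0 over the interferon-stimulated list. Their spread includes the libraries at 2 h, so the lower values of the interferon-stimulated regions there count as noise. These 0 calls thus do not show that the difference is particular to 2 h. The term for KO at 2 h fits the 2 libraries at 2 h exactly. Its spread comes only from how far the genotype difference varies between untreated and 1 h, so its p-values hold no noise of the libraries at 2 h. Of all tested regions 10.2% had an unadjusted edgeR p under 0.05 for this term, against 3.88% for KO untreated and 3.62% for KO at 1 h. This does not show a wider difference at 2 h. The genotype differences untreated and at 1 h, which set the spread of the 2 h term, were the most closely correlated (r of 0.684). Over tested regions the standard deviation of the log2 ratio of KO to WT was 0.562 at 2 h, 0.588 at 1 h and 0.543 untreated.

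The rule for regions whose response differed at both LPS times named Eif4enif1 and Sfi1, Thsd4, Gatad2b, Niban1 and St3gal4, with a lower response in KO, and Opcml, Ksr2, Gm33838, Ank2 and Gyg, with a higher one. The differences at 1 h and 2 h share the same untreated libraries, so 1 untreated value can set the sign at both. In each of these at least 1 library had no island, so that the values depend on the fill. The region over Opcml (chromosome 9, 28376601 to 28393199) held 1359, 185 and 73 normalized reads in WT and had 39, 29 and 37 in KO, of which the value at 1 h was filled. The difference there was thus a fall in WT and not a rise in KO. The region over Eif4enif1 and Sfi1 held between 990 and 1121 normalized reads in every library but WT untreated, where no island was called.

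The island sets overlapped widely between libraries. Of the islands in WT untreated, 92.1% overlapped an island in KO untreated by at least 1 bp, 90.1% one in WT LPS 1 h and 85.6% one in WT LPS 2 h. Of the islands in KO LPS 2 h, 90.1% overlapped one in WT LPS 2 h and 92.1% one in KO LPS 1 h. Between 3.90% and 7.49% of the islands in the H3K27ac libraries overlapped an island in the input by at least 1 bp, and between 0.97% and 4.61% by at least 50% of the shorter island.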

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

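The tests in this part were chosen after the patterns had been seen. The subtraction of the surrounding median, used here for copy number, was however a setting fixed before. The tests for a general loss and a slower response were chosen in place of earlier ones, whose values are also given. Predictions were written after the values except for the input. The bootstrap intervals cover the spread between regions only and hold no noise between libraries.

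In the 2 single libraries at 2 h, 35 of 62 interferon-stimulated regions passed the edgeR term for KO at 2 h, all lower in KO, when adjusted over the list alone with 1 residual degree of freedom, while 0 of 22818 regions passed when adjusted over all, and the 35 share the same 2 libraries and are not independent. A general loss of LPS-induced signal in the KO 2 h library is argued against as the whole cause, since the LPS early response list, fixed before the data, had a median difference of responses at 2 h, KO minus WT, of -0.0139 (bootstrap 95% interval -0.09 to 0.12, 46 regions), while a smaller loss stays open, with -0.33 (-0.61 to 0.25) for the LPS late response list and a log2 ratio of KO to WT at 2 h over other regions higher than untreated of -0.19 when chosen in WT, 0.14 when chosen in KO and 0.0278 when called over both genotypes. A slower response in KO stays open, as the log2 ratio at 2 h minus that at 1 h had a median of -0.0657 (-0.51 to 0.12) over the 17 regions of the LPS late response list, too few to decide, and over other regions higher at 2 h than at 1 h -0.67 when chosen in WT, 0.41 when chosen in KO and -0.0183 when called over both, so that the choice of regions decides the sign. Weak regions missed in the shallow KO library are argued against by the 47 list regions with islands in all 6 libraries and at least 200 mean normalized reads, with a median of -0.74 (-0.87 to -0.60), and copy number by the list's median of -0.85 after subtraction of the median of the surrounding 10 Mb. Also open are a difference particular to these 2 libraries, such as culture state, and a difference between the lines other than Parp14, so an effect of the genotype is a hypothesis that these data cannot separate from those, and the lower Ifnb1 region in KO, at a ratio of 0.223 at 2 h, may belong to the same pattern, which was not tested.

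The input list, which no comparison uses, held its most islands on chromosomes 3 (2877) and 1 (2322), out of 20444, while chromosome X held 3. Most islands lay on other chromosomes, and the 5 windows described next held 12.3% of them all. In 5 windows of 10 Mb, chromosome 1 from 160 to 170 Mb and chromosome 3 from 80 to 120 Mb, islands covered between 16.5% and 28.3% of the window, against a median of 2.47% over 258 windows, and the limit of 15% that set these windows apart was chosen after the input had been examined. A gain of copies in the cells of the H3K27ac libraries would raise their reads there too. The WT untreated regions in these windows had a median log2 of reads per kb 0.29 above other autosomal regions (0.11 to 0.40, 457 regions), between the 0.1 and 0.3 predicted for absence and presence before the value was computed, so the explanations cannot be told apart. The input is labelled RAW 264.7 but the name of its list carries BM. Other cells, a gain particular to the input's cells and the settings of its island calling, which are not given, thus stay open and were not tested.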

How the results depend on the processing

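Leaving out the shifted stretches and the KO term at 2 h were chosen after the data were seen. No paired analysis was possible because each group held 1 library and the labels give no replicate numbers. Time or genotype already stood as a block in the tests. The number of regions differing between KO and WT (1086) was 1873 in the DESeq2 test, 570 with the 10 Mb median subtracted, 577 without the shifted stretches, 706 with the 25th percentile fill and 0 with a fill of 0 reads, and ran from 31 to 1559 with 1 library left out. The LPS 1 h count (7294) was 4659 at 200 reads, where fewer regions were tested, and 4513 with a fill of 0 reads, and ran from 2570 to 8677. The LPS 2 h count (9828) ran from 4858 to 8690, and the count between 1 h and 2 h (2532) was 0 with a fill of 0 reads and ran from 0 to 2678. A library left out leaves 1 residual degree of freedom and assumes that the lone library varies like the others. All other settings gave counts within 1.5 times. Minimum means of 20 reads and none were identical, because no region lay under 20. For a fill of 0 the cause was not tested.

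The counts by the size rule grew at 1.5-fold, by construction, to 8682 (WT 1 h), 10339 (KO 1 h), 11056 (WT 2 h), 10987 (KO 2 h), 4669 (KO against WT untreated), 5436 (1 h) and 4984 (2 h). With islands required in both libraries they fell to 3556 for KO 1 h, 4000 for WT 2 h, 3869 for KO 2 h, and 1076, 1371 and 1324 for KO against WT untreated, at 1 h and at 2 h. With a fill of 0 reads they were 8244 for KO 1 h, 4388 for KO against WT untreated and 3994 at 1 h. The fill thus decides part of each count and, for KO against WT untreated (2654 higher and 1734 lower with 0 reads), for WT 1 h (3736 and 3384) and for KO 1 h (4128 and 4116), the direction of the split. The same held for the edgeR calls at LPS 1 h, with 2793 and 1720 for 0 reads and 4284 and 2168 for the 25th percentile. The interferon-stimulated median of KO against WT at 2 h ran from -0.85 to -0.73 over its alternatives and the difference of responses from -0.82 to -0.70, with -0.74 for the KO term.

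Of the named regions, 4 changed sign, none of them past the threshold there. Tirap and Tyk2, on chromosome 9, went to log2 ratios of -0.0644 and -0.16 for KO against WT with the 10 Mb median subtracted, which removes the shift of that stretch. Ms4a1 went to 0.21 for KO against WT and S100a8 to 0.0161 at LPS 2 h with the 25th percentile fill, the cause of which was not tested. Over the named regions 2769 values kept their direction and side of the threshold, 106 no longer passed and 17 passed newly, and with a library left out these counts were 921, 140 and 7. Of list medians 1586 stayed within their bootstrap interval and 44 left it, and 248 and 16 with a library left out. Requiring an overlap of at least 50% of the shorter island moved 11 of 36 island overlaps beyond their binomial interval. Depth differed between libraries, with 64.9 reads per kb of island in KO LPS 2 h, 66.7 in WT untreated and 146 in KO LPS 1 h, and 7915, 8721 and 6126 regions without an island.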

Other observations

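Regions of some gene groups outside the innate response changed with time. The osteoclast list had a median log2 ratio of KO to WT of 0.32 at 2 h, above 99.8% of random lists, with a bootstrap 95% interval over its 11 regions of -0.39 to 0.52, and Ctsk, with its region shared with Arnt, held 1583 normalized reads in WT untreated and 231 in KO. The sterol and LXR list had small negative medians for KO against WT at each time, -0.13 untreated, -0.09 at 1 h and -0.07 at 2 h, while 1 of its 18 regions passed in each direction when adjusted over the list alone. In the IL-4 and STAT6 list Ccl24, an eosinophil chemokine, had 60 normalized reads in WT and 347 in KO at 2 h, and Arg1, the arginase of alternatively activated macrophages, 45 and 181, with KO to WT differences over the 3 times that did not pass (edgeR adjusted p = 0.448 and 0.470), while Ccl24 passed the term for KO at 2 h, a test chosen after the values were seen, when adjusted over its list alone (adjusted p = 0.00427) and not over all regions (0.246). At 1 h of LPS 5 sterol and LXR regions rose and 2 fell, with Abca1 2.21-fold higher and Hmgcs1 1.58-fold higher, 4 osteoclast regions rose and 2 fell, with Ocstamp 3.33-fold higher, and 6 IL-4 and STAT6 regions rose and 3 fell. The IL-4 and STAT6 regions that fell were 4 under total reads and under housekeeping size factors, and 1 under cyclic loess offsets. In the PARP family 8 regions rose at 1 h and 2 fell, with Parp8 2.23-fold lower (3 and 2 under total reads, 5 and 2 under cyclic loess offsets), in the housekeeping list 2 rose, Actb and Ywhaz, and among the markers of other cell types 1 rose and 3 fell. Without KO LPS 1 h, or without either untreated library, the calls at Hmgcs1, Actb and Ywhaz were lost. Under total reads the 2 housekeeping regions at 1 h that passed were lower and none was higher.

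The tests of explanations in this paragraph and the next were chosen after the patterns had been seen, though the cyclic loess offsets were a setting fixed before. Predictions for intergenic regions and for the trend were written before their values and that for the splits after. The stretches of chromosome 9 and distal chromosome 4 that were higher in KO at every time may be explained by a gain of copies in the KO line, as a hypothesis. The 97 intergenic regions there had a median log2 ratio of 0.43 (bootstrap 95% interval 0.30 to 0.59), where at least 0.4 was predicted, but they were among the regions on which the stretches were chosen, which favours high values. A trend of the ratio with mean reads is argued against, since under cyclic loess offsets the median was 0.54 (0.52 to 0.56). No DNA measurement of the KO line is used here, so a broad change of acetylation along these stretches, or a loss of copies in the WT cells, stays open. The stretches hold Isg15 and Pml of the interferon-stimulated list and members of other lists, whose ratios include the shift.

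For KO against WT over the 3 times, the 6 libraries can be split into 3 and 3 in 10 ways, too few for a share under 0.05. The real split called 1086 regions by edgeR, the highest of the other splits called 0, and the real split was the 1 split with as many. Of the 10 only 4 put 1 library of each time in each arm. The remaining 6 put both libraries of a time together. With time as a block, their contrast rests on the KO and WT libraries of a single time. Only 3 others are thus comparable (at most 0 called, and at most 591 at an unadjusted p under 0.05), and chance cannot be told apart by these splits.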
